A study of Mus musculus with 16 samples.

How the data were processed

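RNA abundance was measured by sequencing in mouse bone marrow-derived monocytes, myeloid cells cultured with macrophage colony-stimulating factor (M-CSF), the growth factor that drives monocytes towards macrophages. Per the labels, cells of 4 wild-type animals were each given vehicle, the compound PFM037, tumour necrosis factor (TNF) or PFM037 together with TNF, and RNA was taken after 24 h. PFM037 is known here by its code name alone, and its target and dose are not given in the sources used here. The 16 libraries form 4 groups of 4, with every animal present once in every group.

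Per the labels' protocols, total RNA was purified on spin columns, 500 ng were put into a stranded, poly(A)-selecting TruSeq kit, and single 75-base reads were taken on a NextSeq 500. The submitters' processing notes name STAR 2.5.3a (a read aligner), featureCounts (a read counter) and limma, together with the mouse assembly mm10 (GRCm38), and the order and settings of these tools are not given in the sources used here. The deposited table holds the authors' read counts per gene, as whole numbers that are not normalized, with 1 column per library. The annotation release and the strand setting of the counting are likewise not given in the sources used here. Reads that fall where genes overlap cannot be assigned with certainty, and genes with near-identical copies can lose or gain reads. The table has 50508 genes, of which 30556 had a count in at least 1 library. Of these, 26 carry a date in place of a gene symbol, and the 19 of them that passed the filter were tested without a name. Library totals ran from 9403232 to 21017905 counts. Both extremes lie in the TNF group, and low genes are measured less precisely in its shallower libraries.

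Counts were tested in R 4.3.3 with edgeR 4.0.16, using its quasi-likelihood F-test, TMM scaling and its filterByExpr filter (minimum count 10, minimum total 15), which kept 13856 genes. A single model held a mean for each group over all 16 libraries, so that the groups shared an estimate of the spread. The comparisons were TNF against vehicle, PFM037 against vehicle, PFM037+TNF against TNF, PFM037+TNF against PFM037, PFM037+TNF against vehicle, and the interaction of both treatments. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. Fold changes come from the model. Levels are given as CPM, counts scaled to a fixed effective library total with the TMM factors, as mean ± SD over 4 animals.

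The model without an animal term was the main one, and the model with the animal as a block was its alternative. The comparisons, both models, the gene lists, the rule for named genes and the alternatives in scaling, filter, tool and left-out libraries were chosen before the data were examined. The pairing is real, because the labels give the same 4 animals in every group. Deviations from the group means correlated at 0.497 to 0.777 between libraries of the same animal, and the best partner of a library in another group came from the same animal in 45 of 48 cases. Between animals 1 and 2, or 3 and 4, the correlation was 0.307 to 0.609, and across these pairs of animals it was -0.677 to -0.411. The blocked value is therefore given beside results whose call or size it changed.

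Genes are named by rule. Among genes past the threshold, with a mean of at least 5 CPM, a proper symbol and the same sign of change in all 4 animals, the 8 highest and 8 lowest fold changes were taken (4 and 4 for PFM037+TNF against vehicle and for the interaction). The 3 members with the smallest adjusted p of each called list were added, as were Tnf, Tnfrsf1a, Tnfrsf1b, Csf1, Csf1r, Nfkbia and Hmox1 in every comparison of treatments. In PFM037 against vehicle, PFM037+TNF against TNF and the interaction the model without a block called no gene, so there the rule was applied to the blocked model, a decision made after the data had been seen.

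For gene groups, 28 lists from textbook knowledge were tested with camera in limma 3.58.1 on voom log2 CPM, with the preset correlation of 0.01 between members, and again with an estimated correlation. Camera asks whether a list moves relative to other genes. With the preset correlation the p-value is small when members rise and fall together from animal to animal for any reason, so list calls that are lost with the estimated correlation are weak evidence. Fry, a self-contained test of whether members move on balance, was run as well, and its blocked form was added after the data had been seen. The lists include markers of other bone marrow cells that such cultures can hold. Emr4, a symbol in the macrophage maturation list, was absent from the table.

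Alternatives to the model without a block were size factors of DESeq2, library size alone, no filter beyond a count above 0, a stricter filter of at least 5 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, and each library left out in turn. For the blocked model, limma-voom, DESeq2, library size alone, the stricter filter, each animal left out and each pair of animals alone were added after the data had been seen. Comparisons that share libraries were set beside 20 simulated sets of unchanged groups and beside splits of the shared libraries.

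The procedure was tested on simulated counts for PFM037 against vehicle, drawn for 13703 genes with known changes. Without a block edgeR recovered 26.6%, 64.1% and 87.3% of genes changed 1.5-fold, 2-fold and 4-fold and called 0 others, and with the block it recovered 65.6%, 87.5% and 100% and called 9 others. For a list shifted by 0.3 on the log2 scale, camera with the preset correlation called it and 0 of the 27 other lists. With an estimated correlation it missed that list without a block (adjusted p = 0.812) and called it with the block (adjusted p = 7.59e-06). Noise was drawn for each gene independently. The 0 of 27 other lists therefore does not show how the preset test treats unchanged lists whose members vary together.

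Gene positions are from GENCODE M21 on GRCm38, in which 94.3% of the table's symbols were found. Of 186 named genes, 8 have exons that overlap a gene on the same strand and 38 on the opposite strand. Counts of such genes may be shared with the neighbour, which bears among others on Ear1, Top2a, Ctsd, Ctsl, Ifi203, Trim47 and Olfm4 on the same strand, and on Mmp12, Tgm2, Plpp1, Gpr84, Gas6 and Ankrd37 on the opposite strand. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.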

Results

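Messenger RNA was sequenced from bone marrow-derived monocytes of 4 wild-type mice, cultured with M-CSF for 24 h in the presence of vehicle, the compound PFM037, TNF, or PFM037 and TNF together. The design asks which transcripts TNF changes, which transcripts PFM037 changes with and without TNF, and whether the effect of either depends on the other. Each of the 4 groups held 4 libraries, 1 per animal. Total counts per library ran from 14114703 to 20125134 for vehicle, from 11142804 to 18845228 for PFM037, from 9403232 to 21017905 for TNF and from 15092524 to 18694616 for PFM037+TNF. The TNF libraries of animals 3 and 4 were thus the shallowest of their group, with 11186760 and 9403232 counts. No pair of libraries within a group matched within sampling noise, so all 16 were counted as separate replicates.

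The first principal component of log2 CPM carried 46.2% of the variance and parted animals 1 and 2 from animals 3 and 4, and the second carried 17.2% and parted libraries with TNF from those without. Interferon-stimulated genes marked the animals most strongly, their median being higher by 2.54 ± 0.54 on the log2 scale in animals 3 and 4 than in animals 1 and 2 (SD over the 4 groups). Markers of mast cells, basophils and eosinophils went the other way, with a difference of -1.73 ± 0.23. All treatment comparisons were made in every animal, so this division does not fall between the groups compared, but it widens the spread within them.

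**Figure D1:**
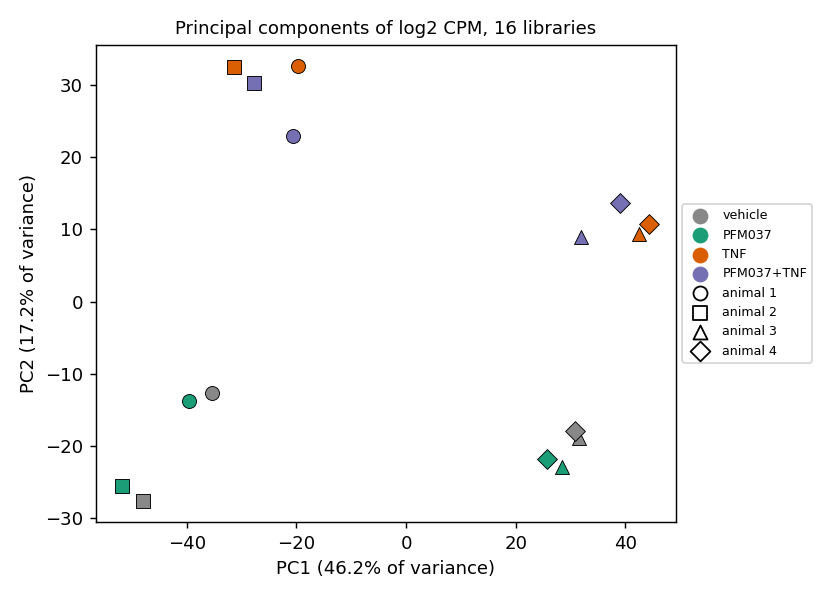
Principal components of log2 CPM for the 16 libraries, with the first component on the x axis, the second on the y axis, colours for the 4 treatment groups and shapes for the 4 animals. Libraries of animals 1 and 2 lie at or below -19.7 on the first component and those of animals 3 and 4 at or above 25.8, and libraries with TNF lie higher on the second component than libraries without TNF.

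TNF, a cytokine that signals through NF-kB, was compared with vehicle to find the transcripts it changes in monocytes already exposed to M-CSF. Ptges, which encodes a prostaglandin E synthase, rose from 7.78 ± 0.972 to 51.1 ± 14.6 CPM (SD, n = 4), a fold change of 6.59 (log2 2.72, SE 0.20, adjusted p = 4.13e-06). Plpp1, a lipid phosphate phosphatase, rose from 1.28 ± 0.686 to 10.1 ± 0.596 CPM, or 7.95-fold (log2 2.99, SE 0.32, adjusted p = 0.000128). Gpr84, a receptor for medium-chain fatty acids, rose from 13.0 ± 3.49 to 83.3 ± 23.7 CPM, or 6.41-fold (log2 2.68, SE 0.24, adjusted p = 2.22e-05). The macrophage scavenger receptor Marco rose 6.08-fold (SE 0.44 on the log2 scale), and uridine phosphorylase Upp1 5.16-fold (SE 0.37). Argininosuccinate synthase Ass1 rose 4.88-fold (SE 0.18), the formyl peptide receptor Fpr1 4.65-fold (SE 0.42) and the neutrophil-attracting chemokine Cxcl1 4.58-fold (SE 0.32), each in 4 of 4 animals. Gm5424, a close copy of Ass1, gave a log2 change of 2.17, so reads of the pair may have been shared. On GRCm38, Ptges lies on chromosome 2 at 30889471 to 30929863 (minus strand), Plpp1 on chromosome 13 at 112800792 to 112867894 (plus strand) and Gpr84 on chromosome 15 at 103308235 to 103310612 (minus strand), all protein-coding genes.

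With TNF, Gas6, the secreted ligand of the Axl and Mertk receptors that serve uptake of dying cells, fell from 42.3 ± 13.7 to 12.0 ± 4.39 CPM (log2 -1.82, SE 0.42, adjusted p = 0.0278). Pparg, a lipid-sensing nuclear receptor, fell from 26.0 ± 8.95 to 9.23 ± 2.92 CPM (log2 -1.48, SE 0.26, adjusted p = 0.00603). Id1, an inhibitor of helix-loop-helix factors, fell to 0.359 of vehicle (SE 0.17 on the log2 scale), Sel1l3 to 0.394 (SE 0.29), the ubiquitin ligase Rnf144b to 0.415 (SE 0.13) and the brain-type creatine kinase Ckb to 0.469 (SE 0.12), each in 4 of 4 animals. Gas6 missed the threshold when vehicle 1, vehicle 4 or any single TNF library was left out (adjusted p = 0.0561 to 0.0889). Sel1l3 did so without vehicle 1, vehicle 2, TNF 2, TNF 3 or TNF 4 (adjusted p = 0.0588 to 0.0714). Fits with single libraries left out, here and below, had no block. All 371 genes called for TNF without a block were called again with it. Gas6 lies on chromosome 8 at 13465374 to 13494490 (minus strand) and Pparg on chromosome 6 at 115360951 to 115490399 (plus strand).

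**Figure D2:**
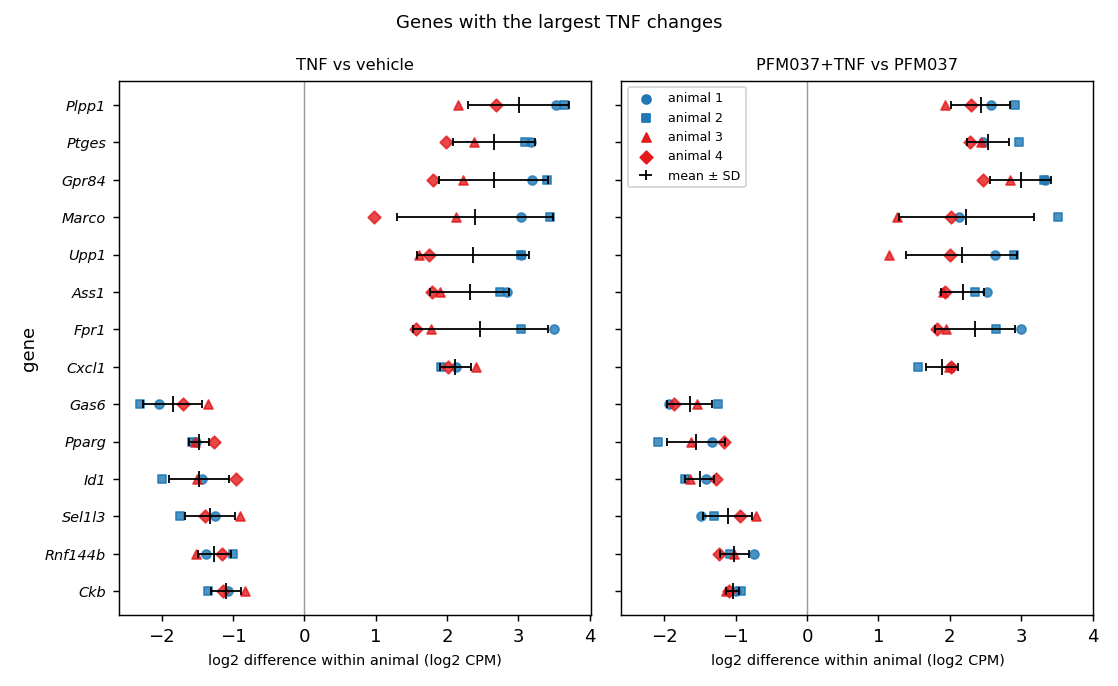
Within-animal log2 differences (log2 CPM, x axis) of 14 genes among those with the largest TNF changes (y axis), without PFM037 on the left and with PFM037 on the right, 1 point per animal with the mean and SD over 4 animals. The 8 genes at the top lie to the right of 0 in all 4 animals and the 6 at the bottom to the left, in both panels.

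Among gene groups, the 30 measured genes of the NF-kB and TNF response moved furthest, with a median log2 change of 1.07 and 29 of 30 members above 0. Of these, 11 rose and 0 fell over all genes tested, 17 rose when adjusted over the list alone, and 28 rose with the animal as a block. The list's camera test gave an adjusted p = 7.55e-23, and adjusted p = 0.123 with an estimated correlation. Tnfaip3, which encodes the NF-kB inhibitor A20, rose 4.22-fold (SE 0.19 on the log2 scale), the mitochondrial superoxide dismutase Sod2 3.94-fold (128 ± 16.2 to 503 ± 96.5 CPM) and Nfkbia, the inhibitor IkB alpha, 3.20-fold (181 ± 9.87 to 577 ± 120 CPM). Tnf itself rose 2.96-fold, from 51.1 ± 2.21 to 151 ± 52.3 CPM (adjusted p = 0.00745). Of 16 measured chemokines, 4 rose and 0 fell (5 and 0 adjusted over the list alone, 8 and 3 with the block), the median being 0.50 (camera adjusted p = 0.0084). That call was lost with adjusted p = 0.465 with an estimated correlation. Cxcl2, another neutrophil attractant, rose 4.00-fold, and Ccl22, which attracts T cells, rose 2.66-fold but missed the threshold without vehicle 1, vehicle 2, vehicle 4, TNF 1 or TNF 2 (adjusted p = 0.0722 to 0.0958).

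Of 28 measured NRF2 targets and heme catabolism genes, 6 rose and 0 fell with TNF (15 and 1 adjusted over the list alone, 18 and 1 with the block), with a median of 0.62 (camera adjusted p = 2.87e-09, but adjusted p = 0.291 with an estimated correlation). They included the cystine transporter Slc7a11 (4.40-fold, SE 0.31 on the log2 scale), the glutathione transferase Gsta3 (3.54-fold, SE 0.38) and the ferritin heavy chain Fth1 (1.77-fold, SE 0.14), while heme oxygenase Hmox1 had a log2 change of 0.16 (SE 0.19, adjusted p = 0.805). Gsta3 missed the threshold without vehicle 2, vehicle 3 or TNF 2 (adjusted p = 0.0511 to 0.0649). In the glycolysis and hypoxia list 25 of 27 members were above 0 and none passed the test, over all genes or adjusted over the list alone, whereas 15 rose and 1 fell with the block. Its median was 0.43 (camera adjusted p = 0.0152, adjusted p = 0.941 with an estimated correlation). The glucose transporter Slc2a1 had a log2 change of 0.92 (SE 0.33, adjusted p = 0.201) that passed with the block (0.94, SE 0.08, adjusted p = 9.58e-07), and phosphoglycerate kinase Pgk1 likewise (0.65, SE 0.33, adjusted p = 0.422, against adjusted p = 0.000294 with the block). Of 20 p53 targets, 1 rose, the death receptor Fas at 3.26-fold (adjusted p = 0.0037), and 0 fell (2 and 0 adjusted over the list alone, 7 and 2 with the block), with a list median of 0.26 (camera adjusted p = 0.0152, adjusted p = 0.291 with an estimated correlation).

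Camera called 3 lists downward with TNF, each with the preset correlation and none with an estimated one. Over all 28 lists, up or down, fry called 3 without a block and 10 with it. Of 23 cholesterol synthesis genes 22 were below 0, 4 fell and 0 rose (7 and 0 adjusted over the list alone, 17 and 1 with the block), with a median of -0.38 (camera adjusted p = 4.47e-11, adjusted p = 0.46 with an estimated correlation). Squalene epoxidase Sqle fell to 0.621 of vehicle (SE 0.09 on the log2 scale), the lanosterol demethylase Cyp51 to 0.606 (SE 0.16) and the reductase Dhcr7 to 0.638 (SE 0.15). Cyp51 missed the threshold without vehicle 3, vehicle 4, TNF 1 or TNF 2 (adjusted p = 0.0593 to 0.0797). Dhcr7 did so without vehicle 3, vehicle 4, TNF 1, TNF 2 or TNF 3 (adjusted p = 0.0572 to 0.104). In the cell cycle list 32 of 33 genes were below 0 and the median was -0.36 (camera adjusted p = 8.95e-08, adjusted p = 0.687 with an estimated correlation). None of its members passed over all genes, 2 fell when adjusted over the list alone and 26 fell with the block, among them cyclin Ccnb2 (blocked log2 -0.59, SE 0.08, adjusted p = 4.59e-05) and the mitotic kinase Aurkb (-0.54, SE 0.09, adjusted p = 0.000492). The macrophage maturation list had a median of -0.60 over 27 genes (camera adjusted p = 0.0084, adjusted p = 0.941 with an estimated correlation). In it 3 fell, among them the lipid receptor Trem2 (to 0.63 of vehicle, adjusted p = 0.00234), and 2 rose, among them Marco (5 and 3 adjusted over the list alone, 16 and 6 with the block).

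Without a block, 249 genes rose and 122 fell with TNF, 135 and 20 of them by at least 2-fold. With the animal as a block 1329 rose and 1363 fell, and all 371 genes called without it were called again with the same sign. Scaling by library size alone gave 218 higher and 189 lower without a block, and 1064 higher and 2148 lower with it. The 371 calls became 221 without vehicle 1, 206 without vehicle 2, 225 without TNF 1 and 221 without TNF 2. The blocked count became 1581 without animal 1, 1685 without animal 2 and 1703 without animal 4. Of the fixed receptor and growth factor genes, Tnfrsf1a (log2 -0.14, SE 0.14), Csf1 (0.27, SE 0.41) and Csf1r (0.38, SE 0.31) did not pass. Csf1r passed with the block (0.40, SE 0.07, adjusted p = 0.000823), as did Tnfrsf1b, the second TNF receptor (0.96, SE 0.40, adjusted p = 0.304, and 1.11, SE 0.17, adjusted p = 0.000175 with the block).

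The other 20 lists did not pass camera without a block with TNF. With the block, camera also called the interferon-stimulated genes (median 0.32, adjusted p = 0.000571, adjusted p = 0.683 with an estimated correlation). It likewise called MHC class I antigen presentation (0.17, 0.00118 and 0.489 in the same order), the neutrophil and granule genes (-0.28, 0.000571 and 0.489), LXR and PPAR targets (-0.18, 0.0445 and 0.489) and mitochondrially encoded genes (0.22, 0.0445 and 0.543). Medians without a block were -0.07 for MHC class II, 0.01 for classical monocyte genes, 0.02 for osteoclast genes and -0.25 for alternative activation. They were -0.04 for the unfolded protein and integrated stress response, 0.05 for heat shock, -0.02 for lysosome and autophagy, 0.12 for immediate early genes, -0.07 for pyrimidine, purine and NAD synthesis, and 0.01 for aryl hydrocarbon receptor and glucocorticoid targets. Markers of other cells had medians of 0.09 for dendritic cells, -0.34 for neutrophils, 0.00 for lymphocytes, -0.09 for erythroid cells and megakaryocytes, 0.20 for mast cells, basophils and eosinophils, and 0.01 for stromal and endothelial cells. For the osteoclast, stress response, lysosome, nucleotide synthesis, aryl hydrocarbon receptor, lymphocyte and stromal lists, the median, the mean and the test did not share a sign.

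PFM037 was compared with vehicle to find the transcripts it changes in the absence of TNF. With the animal as a block 2 genes rose and 9 fell. Dusp4, a phosphatase that switches off MAP kinases, fell to 0.537 of vehicle in 4 of 4 animals (blocked log2 -0.90, SE 0.10, adjusted p = 0.000891). Cgnl1, a cell junction protein, fell from 28.3 ± 5.22 to 13.9 ± 5.06 CPM (SD, n = 4, -1.06, SE 0.15, adjusted p = 0.0131). Cd36, a scavenger and fatty acid receptor, fell from 636 ± 373 to 365 ± 169 CPM (-0.75, SE 0.12, adjusted p = 0.0392). Transglutaminase Tgm2 fell to 0.54 of vehicle (SE 0.16 on the log2 scale), coagulation factor F7 to 0.548 (SE 0.16), the betaine and GABA transporter Slc6a12 to 0.616 (SE 0.12), the kinase Pim3 to 0.626 (SE 0.11) and the secretory pathway kinase Fam20c to 0.68 (SE 0.10), each in 4 of 4 animals with the adjusted p between 0.0392 and 0.0453. The ninth, Errfi1, an inhibitor of the EGF receptor, fell by 0.53 (it lies outside the rule and was added after its value was seen). Ear1 and Ear2, ribonucleases of eosinophils, rose 1.82-fold and 1.59-fold (SE 0.14 and 0.12, adjusted p = 0.0392 and 0.0453), Ear1 from 11.0 ± 8.46 to 19.6 ± 14.9 CPM. They belong to a family of near-identical genes whose reads cannot be told apart with certainty.

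Without the block, edgeR called 0 genes, with 223 at an unadjusted p under 0.05 and a smallest adjusted p = 1, and DESeq2 and limma-voom also called 0. The 11 blocked calls became 5 without animal 1, 1 without animal 2, 6 without animal 3 and 0 without animal 4. Blocked scaling by library size alone gave 2 higher and 2 lower. Dusp4 lies on chromosome 8 at 34807297 to 34819894 (plus strand), Cgnl1 on chromosome 9 at 71626509 to 71771602 (minus strand), Cd36 on chromosome 5 at 17781690 to 17888801 (minus strand) and Ear1 on chromosome 14 at 43818765 to 43875517 (minus strand). The fixed genes showed no call in either model, with blocked log2 changes of 0.01 for Tnf (SE 0.16), -0.09 for Tnfrsf1a (SE 0.07), -0.42 for Tnfrsf1b (SE 0.17), 0.35 for Csf1 (SE 0.12), -0.14 for Csf1r (SE 0.07), -0.19 for Nfkbia (SE 0.10) and -0.14 for Hmox1 (SE 0.12).

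**Figure D3:**
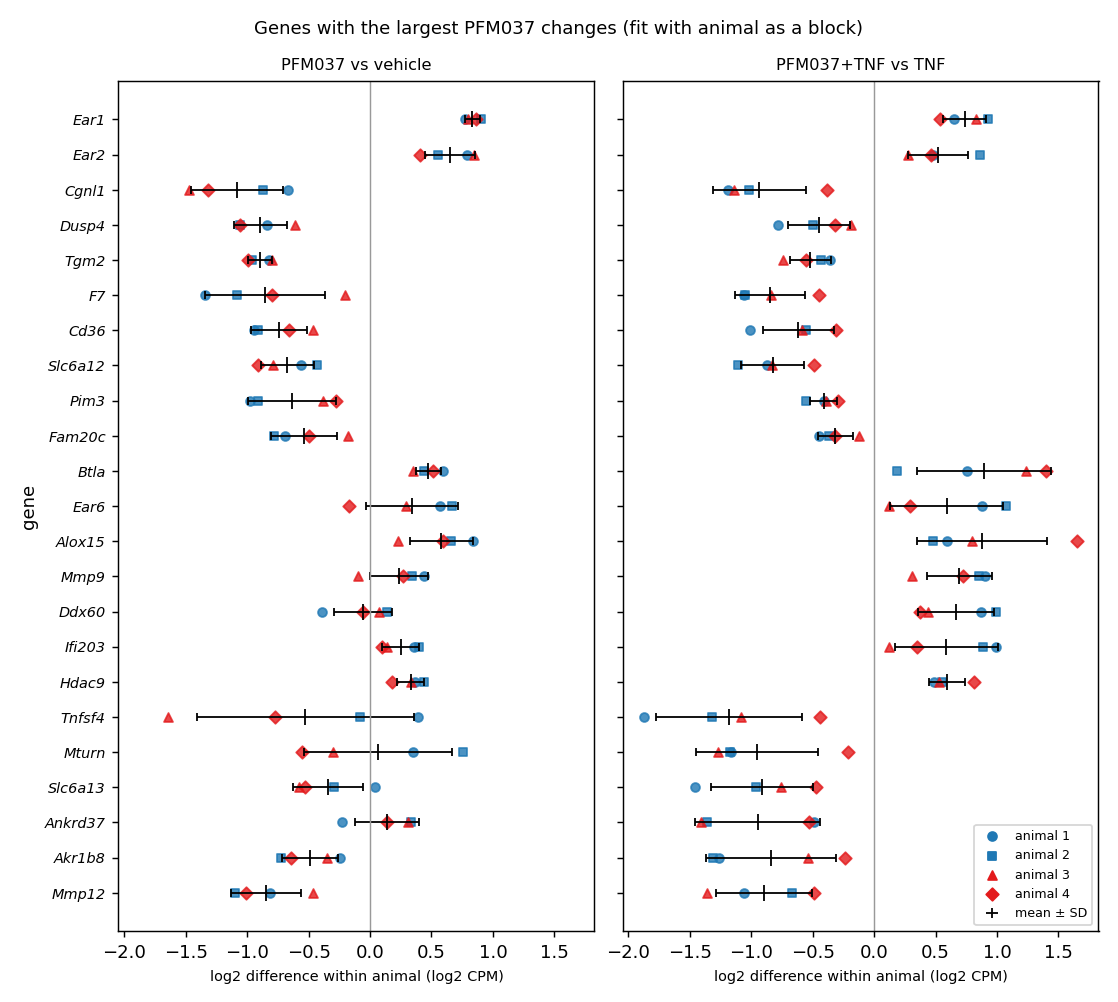
Within-animal log2 differences (log2 CPM, x axis) of the genes with the largest PFM037 changes in the blocked model (y axis), without TNF on the left and with TNF on the right, 1 point per animal with the mean and SD over 4 animals. Dusp4, Cgnl1, Cd36 and Slc6a12 lie to the left of 0 and Ear1 and Ear2 to the right in all 4 animals of both panels.

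With PFM037 camera called 11 of the 28 lists with the preset correlation and 0 with an estimated one. The cell cycle list had 31 of 33 members above 0 and a median of 0.17, and was higher than 0 in each animal, at 0.16 ± 0.05 (camera adjusted p = 3.83e-08, adjusted p = 0.566 with an estimated correlation). Topoisomerase Top2a had a blocked log2 change of 0.34 (SE 0.08, adjusted p = 0.121), the mitotic motor Cenpe 0.35 (SE 0.10, adjusted p = 0.244) and the checkpoint kinase Bub1 0.28 (SE 0.09, adjusted p = 0.283). The lysosome and autophagy list had 25 of 28 members below 0 and a median of -0.13 (camera adjusted p = 2.47e-06, adjusted p = 0.379 with an estimated correlation), with prosaposin Psap at -0.36 (blocked, SE 0.08, adjusted p = 0.0839) and Gpnmb at -0.51 (SE 0.13, adjusted p = 0.162). Its medians in animals 1 to 4 were -0.23, -0.28, -0.03 and -0.09. Cholesterol synthesis had 22 of 23 below 0 and a median of -0.18 (camera adjusted p = 3.84e-06, adjusted p = 0.566 with an estimated correlation), with the feedback regulator Insig1 at -0.26 (SE 0.07, adjusted p = 0.209) and Hmgcs1 at -0.26 (SE 0.08, adjusted p = 0.305). No member of these lists passed over all genes in either model. Adjusted over the list alone none passed without the block, and with it 3 cell cycle genes rose, 4 lysosome genes fell and 1 cholesterol gene fell.

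Camera called further lists downward. The macrophage maturation list had a median of -0.12 (camera adjusted p = 0.000141, adjusted p = 0.566 with an estimated correlation), and lay at -0.34, -0.37, 0.01 and -0.08 in animals 1 to 4, so the shift was mainly in animals 1 and 2. Alternative activation had -0.45 (0.00803 and 0.379 in the same order) and NRF2 targets and heme catabolism -0.15 (0.00803 and 0.568). The medians were for LXR and PPAR targets -0.08 (0.013 and 0.379), for the NF-kB and TNF response -0.16 (0.0273 and 0.743, and 0.02, -0.06, -0.26 and -0.24 in animals 1 to 4) and for chemokines -0.17 (0.0273 and 0.566). With the block Cd36 passed in the macrophage and the lipid list and Tgm2 in the alternative activation list, while 7, 7, 0, 5, 0 and 1 members of these lists, in this order, fell when adjusted over the list alone. The mannose receptor Mrc1, a member of the macrophage and alternative activation lists, had a blocked log2 change of -0.98 (SE 0.24, adjusted p = 0.155), the lectin Clec10a -0.65 (SE 0.15, adjusted p = 0.121), the lipid droplet protein Plin2 -0.37 (SE 0.08, adjusted p = 0.1) and the fatty acid binding protein Fabp5 -0.41 (SE 0.10, adjusted p = 0.151). Of the NRF2, NF-kB and chemokine lists, Fth1 had -0.29 (SE 0.09, adjusted p = 0.331), Il1b -0.52 (SE 0.20, adjusted p = 0.44) and Ccl6 -0.29 (SE 0.08, adjusted p = 0.219). Fry with the block called alternative activation (adjusted p = 0.0346) and, upward, the mast cell, basophil and eosinophil list (adjusted p = 0.0351) among the 28 lists.

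Markers of other bone marrow cells were tested in the same comparison. The mast cell, basophil and eosinophil list had 15 of 15 members above 0 and a median of 0.36, with 0.54, 0.4, 0.02 and 0.16 in animals 1 to 4 (camera adjusted p = 0.0569, and 8.17e-11 with the block, where it was adjusted p = 0.0897 with an estimated correlation), with Prss34, a basophil protease, at a blocked 0.52 (SE 0.10, adjusted p = 0.0548). Lymphocyte markers had a median of 0.26 (camera adjusted p = 0.0101, adjusted p = 0.556 with an estimated correlation), and dendritic cell markers 0.19 (0.0273 and 0.379 in the same order), with Siglech at 0.47 (SE 0.15, adjusted p = 0.32). No member of these lists passed over all genes, and 6 mast cell, basophil and eosinophil genes rose with the block when adjusted over the list alone. Neutrophil and granule genes had 0.13 (0.0789, but 6.32e-05 with the block and adjusted p = 0.313 with an estimated correlation), with Ly6g at 0.39 (SE 0.14, adjusted p = 0.386). Erythroid and megakaryocyte markers had 0.05 and stromal and endothelial markers 0.01, and neither passed. With the block camera also called osteoclast genes (-0.11, adjusted p = 0.0323), glycolysis (-0.07, 0.037), heat shock (0.06, 0.0228) and nucleotide synthesis (0.06, 0.0162), none of which held with an estimated correlation (adjusted p = 0.216, 0.657, 0.216 and 0.311). The median and the test differed in sign for interferon-stimulated, MHC class I, classical monocyte and stromal genes.

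PFM037+TNF was compared with TNF to find what PFM037 changes in TNF-treated monocytes. With the animal as a block 74 genes rose and 114 fell, 0 and 17 of them by at least 2-fold. The neighbouring transporter genes Slc6a13 and Slc6a12 both fell. Slc6a13 went from 14.4 ± 3.20 to 7.51 ± 0.645 CPM (SD, n = 4, blocked log2 -0.94, SE 0.15, adjusted p = 0.0181), and Slc6a12 from 93.5 ± 25.4 to 54.5 ± 21.1 CPM (-0.84, SE 0.12, adjusted p = 0.0181). Tnfsf4, a TNF-family ligand that costimulates T cells, fell from 32.8 ± 29.6 to 12.4 ± 10.6 CPM (-1.30, SE 0.25, adjusted p = 0.0244). Mmp12, the macrophage elastase, fell from 187 ± 74.4 to 98.7 ± 31.6 CPM (-0.88, SE 0.19, adjusted p = 0.0397). Mturn fell to 0.503 of TNF alone (SE 0.21 on the log2 scale), Cgnl1 to 0.521 (SE 0.15), the hypoxia-responsive Ankrd37 to 0.524 (SE 0.21) and the aldo-keto reductase Akr1b8 to 0.541 (SE 0.15), each in 4 of 4 animals. Slc6a13 lies on chromosome 6 at 121300227 to 121337733 and Slc6a12 at 121343076 to 121365775 of the same chromosome and strand (plus), Tnfsf4 on chromosome 1 at 161395409 to 161418410 (plus strand) and Mmp12 on chromosome 9 at 7344381 to 7369499 (plus strand, overlapping Mmp1b on the other strand).

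Genes that rose included Btla, an inhibitory lymphocyte receptor, from 3.65 ± 0.831 to 6.92 ± 1.60 CPM (blocked log2 0.87, SE 0.17, adjusted p = 0.0244), and Mmp9, a gelatinase, from 162 ± 50.7 to 265 ± 102 CPM (0.70, SE 0.13, adjusted p = 0.0234). The eosinophil ribonucleases Ear6 and Ear1 rose 1.68-fold (SE 0.16 on the log2 scale) and 1.66-fold (SE 0.14), the lipoxygenase Alox15 1.64-fold (SE 0.16), the antiviral helicase Ddx60 1.57-fold (SE 0.14), each in 4 of 4 animals with the adjusted p between 0.0234 and 0.0456. The interferon-inducible Ifi203 rose by 0.58 on the log2 scale (SE 0.13, adjusted p = 0.0456) and the histone deacetylase Hdac9 by 0.58 (SE 0.12, adjusted p = 0.0375). Without the block edgeR called 0 genes, with 515 at an unadjusted p under 0.05 and a smallest adjusted p = 0.478, limma-voom called 0, and DESeq2 called 10, of which 3 were higher and 7 lower. The 188 blocked calls became 1 without animal 1, 60 without animal 2, 27 without animal 3 and 3 without animal 4. Blocked scaling by library size alone gave 117 higher and 87 lower, so the balance of rises and falls turned with the scaling. Blocked DESeq2 called 185 higher and 236 lower. The fixed genes were not called in either model, with blocked log2 changes of -0.08 for Tnf (SE 0.16), -0.13 for Tnfrsf1a (SE 0.07), -0.41 for Tnfrsf1b (SE 0.17), 0.10 for Csf1 (SE 0.12), -0.15 for Csf1r (SE 0.07), -0.06 for Nfkbia (SE 0.10) and -0.41 for Hmox1 (SE 0.12).

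With PFM037 added to TNF, camera called 7 of the 28 lists with the preset correlation and 0 with an estimated one, while fry called 0 without a block and 5 with it. In the glycolysis and hypoxia list 25 of 27 members were below 0, 4 fell with the block (17 adjusted over the list alone, and 0 without the block), and the median was -0.34 (camera adjusted p = 0.000391, adjusted p = 0.886 with an estimated correlation). Its medians in animals 1 to 4 were -0.05, -0.21, -0.59 and -0.38, so the shift was mainly in animals 3 and 4. The 4 included Slc2a1 at a blocked -0.37 (SE 0.08, adjusted p = 0.0397) and the triose phosphate isomerase Tpi1 at -0.46 (SE 0.10, adjusted p = 0.0426). Among NRF2 targets 26 of 28 were below 0, 2 fell with the block (14 down and 1 up adjusted over the list alone), and the median was -0.32 (camera adjusted p = 2.25e-07, adjusted p = 0.639 with an estimated correlation). The biliverdin reductase Blvrb fell by 0.40 (SE 0.09, adjusted p = 0.0456) and the glutathione transferase Gstm1 by 0.38 (SE 0.09, adjusted p = 0.0471). In the lysosome list 26 of 28 were below 0 and 2 fell with the block (8 adjusted over the list alone), Psap by 0.34 (SE 0.08, adjusted p = 0.0397) and Gpnmb by 0.53 (SE 0.13, adjusted p = 0.049), with a median of -0.16 (camera adjusted p = 1.67e-05, adjusted p = 0.639 with an estimated correlation) and -0.25, -0.26, -0.03 and -0.07 in animals 1 to 4.

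Camera called further lists upward, again with the preset correlation alone. In the cell cycle list 29 of 33 were above 0 and 4 rose with the block (21 adjusted over the list alone, and 1 without the block), with a median of 0.24 (camera adjusted p = 1.27e-08, adjusted p = 0.745 with an estimated correlation). Top2a rose from 239 ± 26.0 to 327 ± 17.1 CPM (blocked 0.45, SE 0.08, adjusted p = 0.0195), the ribonucleotide reductase Rrm1 by 0.34 (SE 0.07, adjusted p = 0.0407) and the replication factor Mcm4 by 0.34 (SE 0.08, adjusted p = 0.0432). Among neutrophil and granule genes 21 of 23 were above 0 and 4 rose with the block (11 up and 1 down adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.00132, adjusted p = 0.886 with an estimated correlation). Olfactomedin Olfm4 rose by 0.48 (SE 0.09, adjusted p = 0.0234) and lactoferrin Ltf by 0.57 (SE 0.11, adjusted p = 0.0244), both contents of neutrophil granules. Of 30 interferon-stimulated genes 29 were above 0, 1 rose with the block, Ifit2 by 0.49 (SE 0.11, adjusted p = 0.0471), and 13 did so adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.0296, adjusted p = 0.986 with an estimated correlation). Their median was 0.60 and 0.64 in animals 1 and 2 and 0.05 and 0.22 in animals 3 and 4.

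Dendritic cell markers had a median of 0.22 (camera adjusted p = 0.0296, 0.0537 with the block, and adjusted p = 0.639 with an estimated correlation), and 0 members passed. With the block camera also called chemokines (median -0.22, adjusted p = 0.00298, adjusted p = 0.185 with an estimated correlation), alternative activation (-0.32, 0.00227 and 0.158 in the same order), mast cell, basophil and eosinophil markers (0.24, 1.04e-05 and 0.158), LXR and PPAR targets (-0.08, 0.00752 and 0.185) and heat shock genes (0.11, 0.0111 and 0.185). Cxcl1 fell by 0.63 (SE 0.15, adjusted p = 0.0493), Cd36 by 0.60 (SE 0.12, adjusted p = 0.0375) and Plin2 by 0.37 (SE 0.08, adjusted p = 0.0397) with the block, while the interferon-inducible chemokine Cxcl10 was at 0.88 (SE 0.22, adjusted p = 0.06). Lymphocyte markers had a median of 0.09, erythroid and megakaryocyte markers -0.08, stromal and endothelial markers 0.07, the NF-kB and TNF response -0.02 and macrophage maturation -0.01, and none of these lists passed. For classical monocyte, cholesterol, p53 and nucleotide synthesis genes the median, the mean and the test did not share a sign.

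PFM037+TNF was compared with PFM037 to see the effect of TNF in the presence of the compound. Gpr84 rose 8.20-fold, from 11.0 ± 0.533 to 90.1 ± 21.6 CPM (SD, n = 4, log2 3.04, SE 0.24, adjusted p = 6.14e-06), and Ptges 5.90-fold, from 5.99 ± 0.866 to 35.4 ± 6.56 CPM (2.56, SE 0.20, adjusted p = 6.14e-06). The apolipoprotein L gene Apol7c rose 5.79-fold (SE 0.61 on the log2 scale), Plpp1 5.60-fold (SE 0.32), Marco 5.15-fold (SE 0.45), the TNF receptor adaptor Traf1 5.02-fold (SE 0.58), Tnfaip3 4.88-fold (SE 0.19) and the surface receptor Slamf8 4.78-fold (SE 0.34). Gas6 fell to 0.305 of PFM037 alone (SE 0.42), Pparg to 0.341 (SE 0.27), Id1 to 0.353 (SE 0.17) and Sel1l3 to 0.44 (SE 0.29). Rnf144b and Ckb fell to 0.486 (SE 0.13 and 0.12), the secreted glutathione peroxidase Gpx3 to 0.521 (SE 0.19) and the ubiquitin ligase Trim47 to 0.526 (SE 0.22), each in 4 of 4 animals. Traf1 and Sel1l3 missed the threshold when any single library of either group was left out (adjusted p = 0.0602 to 0.145 and 0.0512 to 0.147), Apol7c for all but PFM037 1 (0.0583 to 0.12) and Gas6 for all but PFM037 2 (0.0616 to 0.146). Gpx3 missed it without PFM037 2, PFM037_TNF 2 or PFM037_TNF 4 (0.0576 to 0.0666), and Trim47 without PFM037 1, PFM037 3, PFM037_TNF 1, PFM037_TNF 2 or PFM037_TNF 4 (0.0838 to 0.131). These fits had no block. With the block all 312 genes called without it were called again with the same sign.

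In this comparison camera called 7 of the 28 lists with the preset correlation and 0 with an estimated one, while fry called 2 without a block and 10 with it. Of the NF-kB and TNF response 12 rose and 0 fell (19 and 0 adjusted over the list alone, 28 and 0 with the block), with a median of 1.22 (camera adjusted p = 1.03e-24, adjusted p = 0.0936 with an estimated correlation), among them Sod2 (3.86-fold), Nfkbia (3.50-fold) and Tnf (2.75-fold, adjusted p = 0.013). Of chemokines 2 rose (4 adjusted over the list alone, 8 up and 2 down with the block), Cxcl1 3.83-fold and Cxcl2 3.53-fold, with a median of 0.31 (camera adjusted p = 0.00584, adjusted p = 0.586 with an estimated correlation). Of NRF2 targets 3 rose (11 up and 1 down adjusted over the list alone, 17 and 2 with the block), Slc7a11 3.58-fold, Fth1 1.74-fold and the iron-recycling regulator Spic 4.61-fold, with a median of 0.42 (camera adjusted p = 5.42e-05, adjusted p = 0.586 with an estimated correlation). Of p53 targets 2 rose (2 adjusted over the list alone, 9 up and 1 down with the block), Fas 3.38-fold and the cell cycle inhibitor Cdkn1a 1.44-fold, with a median of 0.23 (camera adjusted p = 0.00584, adjusted p = 0.176 with an estimated correlation). Spic missed the threshold without PFM037 1, PFM037 2, PFM037_TNF 3 or PFM037_TNF 4 (adjusted p = 0.0583 to 0.089), and Cdkn1a without PFM037 1, PFM037 2, PFM037 3, PFM037_TNF 1 or PFM037_TNF 2 (0.0523 to 0.0801).

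Cholesterol synthesis genes had a median of -0.28 and 1 fell (4 adjusted over the list alone, 11 down and 1 up with the block), Sqle to 0.707 of PFM037 alone (camera adjusted p = 6.35e-05, adjusted p = 0.885 with an estimated correlation). All 33 cell cycle genes were below 0 and none passed, also adjusted over the list alone, whereas 21 fell with the block, such as Ccnb2 (-0.52, SE 0.08, adjusted p = 0.000144) and the survivin gene Birc5 (-0.45, SE 0.08, adjusted p = 0.000482). Their median was -0.30 (camera adjusted p = 9.06e-06, adjusted p = 0.89 with an estimated correlation). Of interferon-stimulated genes none passed, also adjusted over the list alone, and 25 rose with the block, such as the RNA sensor Ifih1 (0.70, SE 0.10, adjusted p = 0.000144) and the deubiquitinase Usp18 (1.20, SE 0.24, adjusted p = 0.00251). Their median was 0.44 (camera adjusted p = 0.0121, adjusted p = 0.977 with an estimated correlation). The blocked camera test added MHC class I (0.25, adjusted p = 6.75e-05, adjusted p = 0.41 with an estimated correlation), glycolysis (0.16, 0.0462 and 0.707) and mitochondrially encoded genes (0.23, 0.0481 and 0.62). The median, the mean and the test did not share a sign for classical monocyte, osteoclast, mast cell, stress response, lysosome and aryl hydrocarbon receptor genes. Of the fixed genes Tnfrsf1b (0.99, SE 0.40, adjusted p = 0.288) and Csf1r (0.36, SE 0.31, adjusted p = 0.673) passed only with the block (adjusted p = 0.000175 and 0.00109), and Tnfrsf1a (-0.18), Csf1 (-0.05) and Hmox1 (-0.09) did not pass in either model.

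TNF in the presence of PFM037 raised 213 genes and lowered 99, 112 and 18 of them by at least 2-fold, and with the block 1475 and 1353. Library size alone gave 186 higher and 167 lower without a block and 1057 higher and 2275 lower with it. The 312 calls became 163 without PFM037 1, 195 without PFM037 2, 192 without PFM037 3, 186 without PFM037_TNF 2, 198 without PFM037_TNF 3 and 171 without PFM037_TNF 4. The blocked 2828 became 1596 without animal 2 and 1434 without animal 4.

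The TNF effects with and without PFM037 share no library. Their log2 fold changes correlated across 13856 genes with r = 0.763 (Spearman's rho 0.717), genes not being independent replicates. Of the genes called without a block, 177 rose in both, against 3.83 for independent lists of those sizes, and 68 fell in both, against 0.872, and none went in opposite directions. With the block 990 rose in both, against 141, and 841 fell in both, against 133, while 1 rose without PFM037 and fell with it. The effects of PFM037 with and without TNF, which also share no library, correlated with r = 0.352 (rho 0.422), with 0.649 under the stricter filter and 0.26 to 0.314 without 1 animal. With the block the 2 genes that PFM037 alone raised, Ear1 and Ear2, were also called higher in TNF-treated cells, against 0.0107 for independent lists. Of the 9 it lowered, 5 were called lower there (Dusp4, Cgnl1, Cd36, Slc6a12 and F7), against 0.074. Ear1 and Ear2 are near-identical genes whose reads may be shared, so their 2 calls may not be separate.

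PFM037+TNF was compared with vehicle to give the sum of both treatments. Gpr84 rose 6.92-fold (log2 2.79, SE 0.24, adjusted p = 2.02e-05), Plpp1 5.86-fold (SE 0.32), Ptges 4.56-fold (SE 0.20) and Ass1 4.35-fold (SE 0.18). Gas6 fell from 42.3 ± 13.7 to 8.89 ± 3.62 CPM (SD, n = 4, log2 -2.25, SE 0.42, adjusted p = 0.0101) and Pparg from 26.0 ± 8.95 to 6.33 ± 1.57 CPM (-2.04, SE 0.27, adjusted p = 0.000875). Fam198b fell to 0.282 of vehicle (SE 0.41 on the log2 scale) and the lectin Clec10a to 0.308 (SE 0.32). Fam198b missed the threshold without vehicle 1, PFM037_TNF 2, PFM037_TNF 3 or PFM037_TNF 4 (adjusted p = 0.0771 to 0.0923). In all 191 genes rose and 174 fell, 88 and 43 by at least 2-fold, and with the block 1771 and 1666. All 365 genes called without a block were called again with it, with the same sign. Library size alone gave 170 higher and 228 lower without a block, and 1483 higher and 1999 lower with it, so the balance turned with the scaling. The 365 calls became 184 without vehicle 1, 179 without vehicle 2, 160 without PFM037_TNF 2, 219 without PFM037_TNF 3 and 211 without PFM037_TNF 4. The blocked 3437 became 2045 without animal 2 and 2119 without animal 4.

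In this comparison camera called 10 of the 28 lists with the preset correlation and 0 with an estimated one, while fry called 4 without a block and 15 with it. NF-kB and TNF response genes rose in 10 cases and fell in 0 (17 and 0 adjusted over the list alone, 27 and 0 with the block, median 0.85, camera adjusted p = 2.42e-19, adjusted p = 0.103 with an estimated correlation). Of dendritic cell markers 2 rose (4 adjusted over the list alone, 7 up and 1 down with the block, median 0.37, adjusted p = 0.00394, adjusted p = 0.103 with an estimated correlation), the migration receptor Ccr7 3.22-fold and the actin-bundling Fscn1 2.98-fold. Ccr7 missed the threshold without vehicle 1, vehicle 2 or PFM037_TNF 1 (adjusted p = 0.0504 to 0.0658). Fscn1 missed it without vehicle 1, vehicle 2, vehicle 4, PFM037_TNF 1, PFM037_TNF 3 or PFM037_TNF 4 (0.0828 to 0.102). Of alternative activation genes 3 fell (4 down and 1 up adjusted over the list alone, 7 and 1 with the block, median -0.24, adjusted p = 0.0326, adjusted p = 0.472 with an estimated correlation), Clec10a, the cytokine Il10 (to 0.296 of vehicle) and the lectin Cd209a (to 0.301). Il10 missed the threshold without vehicle 1 or PFM037_TNF 2 (0.0564 and 0.0647), and Cd209a without vehicle 4, PFM037_TNF 2, PFM037_TNF 3 or PFM037_TNF 4 (0.0507 to 0.084). Of macrophage maturation genes 3 fell, among them Gas6 and Trem2, and 1 rose (7 and 3 adjusted over the list alone, 14 and 6 with the block, median -0.53, adjusted p = 0.0138, adjusted p = 0.919 with an estimated correlation). Trem2 fell from 222 ± 29.6 to 101 ± 8.52 CPM.

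Of lipid genes, 2 of the LXR and PPAR targets fell (5 adjusted over the list alone, 11 down and 2 up with the block, median -0.21, camera adjusted p = 0.00943, adjusted p = 0.322 with an estimated correlation), Pparg and the thiolase Acaa2. Cholesterol synthesis genes fell in 2 cases (12 adjusted over the list alone, 18 with the block, median -0.43, adjusted p = 1.16e-09, adjusted p = 0.467 with an estimated correlation), Sqle and the mevalonate kinase Mvk. With the block this was the single list of any comparison that held with an estimated correlation (adjusted p = 0.0368). Mvk missed the threshold without vehicle 1, vehicle 2, vehicle 4 or any PFM037_TNF library (0.0569 to 0.153). Acaa2 missed it without vehicle 1, vehicle 2 or PFM037_TNF 2 (0.0516 to 0.0644). Of lysosome genes 1 fell, the protease Ctsd to 0.646 of vehicle (2 down and 1 up adjusted over the list alone, 12 and 2 with the block, median -0.13, adjusted p = 0.0495, adjusted p = 0.919 with an estimated correlation), and it missed the threshold without vehicle 1 or PFM037_TNF 2 (0.0567 and 0.0657). Of NRF2 targets 1 rose, Slc7a11 at 3.36-fold (2 adjusted over the list alone, 14 up and 4 down with the block, median 0.25, adjusted p = 0.0138, adjusted p = 0.919 with an estimated correlation). Of p53 targets Fas rose 2.68-fold and the stress cytokine Gdf15 fell to 0.405 (2 up and 1 down adjusted over the list alone, 9 and 2 with the block, median 0.30, adjusted p = 0.0462, adjusted p = 0.345 with an estimated correlation). Fas missed the threshold without vehicle 1 (0.0509) and Gdf15 without PFM037_TNF 2 (0.0599). Interferon-stimulated genes had a median of 0.45 and 0 calls, against 26 with the block (adjusted p = 0.0326, adjusted p = 0.919 with an estimated correlation).

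The blocked camera test of PFM037+TNF against vehicle added 5 lists. They were MHC class I (median 0.31, adjusted p = 0.000315, adjusted p = 0.439 with an estimated correlation), mast cell, basophil and eosinophil markers (0.40, 0.000315 and 0.225 in the same order), heat shock (0.18, 0.0431 and 0.417), cell cycle (-0.09, 0.0184 and 0.834) and mitochondrially encoded genes (0.32, 0.0131 and 0.451). The median, the mean and the test did not share a sign for neutrophil, stress response and nucleotide synthesis genes. Of the fixed genes Tnf rose 2.82-fold (adjusted p = 0.0113) and Nfkbia 3.08-fold (adjusted p = 0.00011). Tnfrsf1b (blocked 0.70, adjusted p = 0.00562), Csf1r (0.25, adjusted p = 0.0181) and Tnfrsf1a (-0.26, adjusted p = 0.00935) passed with the block alone, and Csf1 (0.31) and Hmox1 (-0.21) did not pass in either model.

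The interaction asked whether the effect of PFM037 differed with TNF. No gene passed. Without a block edgeR called 0, with 91 genes at an unadjusted p under 0.05, and with it 0, with 383, and DESeq2 and limma-voom called 0 with and without the block. Camera called 5 lists. The cholesterol synthesis genes had 23 of 23 members above 0 and a median of 0.15 (adjusted p = 3.84e-05), interferon-stimulated genes 0.18 (0.0221) and macrophage maturation 0.10 (0.029), whereas NRF2 targets had -0.17 (0.0221) and glycolysis -0.29 with 26 of 27 below 0 (0.0221). Each was lost, at adjusted p = 0.962 with an estimated correlation, and fry with the block called 0 lists. With the block camera also called neutrophil and granule genes (0.14, adjusted p = 0.00321) and erythroid and megakaryocyte markers (-0.05, 0.0313), both at adjusted p = 0.994 with an estimated correlation. Named members of these 7 lists were Irgm1 (blocked 0.45, SE 0.15), Mertk (0.78, SE 0.22), Ankrd37 (-1.10, SE 0.31), Osgin1 (-0.40, SE 0.14), Hsd17b7 (0.44, SE 0.15), Mmp9 (0.47, SE 0.18) and Ermap (-0.59, SE 0.35), each with an adjusted p = 1.

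Genes that TNF changed were compared with those that PFM037 changed in TNF-treated cells. Without a block none of the 371 was called in PFM037+TNF against TNF. With the block 52 genes that TNF raised were lowered by PFM037, against 10.9 for independent lists, and 36 that TNF lowered were raised, against 7.28, while 2 rose and 11 fell with both, against 7.1 and 11.2. Among the 88 were the named genes Slc6a12, Slc6a13, Tnfsf4, Mmp12, Cxcl1, Slc2a1 and Blvrb, lowered by PFM037, and Btla, Hdac9, Top2a, Mcm4 and Rrm1, raised by it, while Cd36, Plin2 and Gpnmb fell with both. The 88 became 1, 36, 14 and 2 without animal 1, 2, 3 and 4, in this order. Both comparisons use the same TNF libraries, so chance values push genes in opposite directions. Over 20 simulated PFM037+TNF groups without change, at most 1 gene was called against TNF, and with the TNF libraries split between the comparisons 0 were called, so neither gives a value to set beside the 88. Of genes called with TNF with the block, 65.1% had the opposite sign in PFM037+TNF against TNF, against 62.8% in simulation (61.3% to 64.9%) and 61.5% with the libraries split (59.5% to 63.5%, 4 splits). Without a block these shares were 72.8%, 61.9% (56.6% to 66.7%) and 75.7% (69.9% to 82%), and animal differences enter the last, because the split leaves different animals in each comparison. The blocked covariance of fold changes was -0.0361, against -0.0215 on average in simulation and -0.0109 with the libraries split (-0.0173 to -0.0047). With the block the simulated sets called 3484.2 genes for TNF on average, against 2692 in the data. They may thus be less noisy than the data and understate what sharing alone gives.

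The effects of TNF and of PFM037 against vehicle share the vehicle libraries. Their fold changes correlated across genes with r = 0.05 and a covariance of 0.0047, below the 0.0195 that shared libraries gave in simulation (0.0048 and 0.019 with the block). The correlation was -0.101 under the stricter filter and 0.059 to 0.148 without 1 animal, so its sign depends on the filter. With the vehicle libraries split the covariance was -0.026 (-0.0471 to -0.0033), and -0.0228 with the block (-0.0401 to -0.0075). Each split gives the 2 comparisons vehicle libraries of different animals, so without a block animal differences enter both effects with opposite sign. The unblocked split value therefore cannot serve as an estimate free of sharing. With the block 5 genes that TNF raised were lowered by PFM037, against 0.863 for independent lists, and 1 rose and 1 fell with both, against 0.192 and 0.885.

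**Figure D4:**
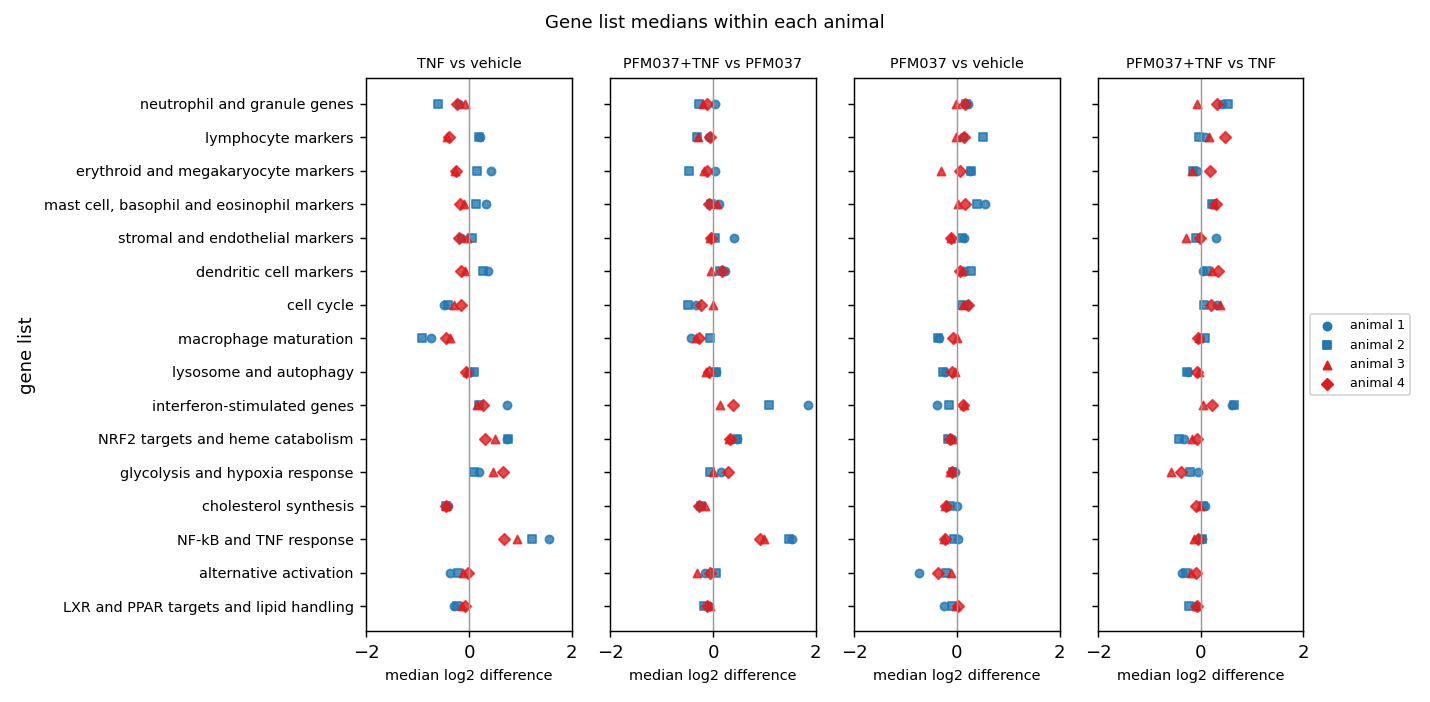
Median log2 difference of each gene list within each animal (x axis) for 16 of the lists (y axis), in 4 panels for TNF without and with PFM037 and for PFM037 without and with TNF, 1 point per animal. The NF-kB and TNF response lies between 0.67 and 1.56 with TNF alone, while cell cycle medians lie above 0 in all 4 animals with PFM037.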

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

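The test of other bone marrow cells for the PFM037 lists and the test on separate animals were chosen only after the result was seen. So were the counts without an animal and all splits of the samples. The depth tests of the first and last patterns and the test of other cells between animals were written before their own results. The depth test of the second pattern uses the splits into separate animals, so in this form it also came after. The animal pairs of the last pattern were themselves chosen after the data had been seen.

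A first pattern, lost by camera with an estimated correlation (adjusted p = 0.566, 0.566 and 0.379), is that with PFM037 against vehicle the cell cycle list lay higher and the macrophage maturation (-0.34, -0.37, 0.01 and -0.08 in animals 1 to 4) and lysosome lists (-0.23, -0.28, -0.03 and -0.09) lower, while in TNF-treated cells the macrophage list was at 0 ± 0.06 (SD over 4 animals). With every library thinned to the smallest total, the blocked cell cycle median was 0.17, against 0.18 in full counts. Thinning keeps each gene's expected share of counts, so it can reveal only effects of low counts. It draws no wider conclusion on sequencing depth. A larger share of all other bone marrow cells together would raise the markers of every other type alike, but a rise of single types would not. The erythroid and megakaryocyte median lay below that of mast cells, basophils and eosinophils by -0.2 ± 0.11 (SD over 4 animals) without TNF and by -0.3 ± 0.13 with it, in 4 of 4 animals each. The mast cell, basophil and eosinophil median itself was above 0 in 4 of 4 animals in both comparisons (0.28 ± 0.23 and 0.25 ± 0.04). That of erythroid cells and megakaryocytes was above 0 in 3 of 4 animals without TNF and in 1 of 4 with it. That contrast was picked from 10 pairs of lists after their medians had been seen, of which 4 stood apart in each comparison, and a rise of single cell types stays open, as does an effect of the compound on the monocytes.

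A second pattern is that PFM037 moved genes that TNF had changed in the other direction, in the blocked model, with 88 genes that became 1, 36, 14 and 2 without animal 1, 2, 3 and 4. With the TNF effect taken from 2 animals and the PFM037 effect from the other 2, no library is shared, and the covariance was below 0 in 6 of 6 splits (highest -0.00346, mean -0.0135). The 6 splits reuse the same 4 animals, so they are not independent, and their correlations ran from -0.185 to -0.021. No spread was computed for the case without an effect, so these splits do not exclude shared TNF libraries as the whole cause. Part of the observed covariance of -0.0361 does come with sharing. In thinned libraries the mean covariance over the splits was -0.0116, so unequal depth at low counts did not account for most of it. Thinning tests no other effect of depth. An effect of PFM037 on the response to TNF stays open as a hypothesis found and tested on the same data. The interaction called 0 genes, and the PFM037 effects with and without TNF, which share no library, correlated with r = 0.346 with the block. An effect of PFM037 that does not need TNF therefore stays open as well. A change in the share of other cells was not tested for this pattern.

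The last pattern is that libraries of animals 1 and 2 stand apart from those of animals 3 and 4 in every group. After thinning, the gap on the first component was 45, so unequal depth at low counts did not account for it. Among lists of other cells, the mast cell, basophil and eosinophil median was lowest, at -1.73 in animals 3 and 4 against 1 and 2, while the erythroid list lay higher by 0.31 ± 0.3 and the stromal list by 0.17 ± 0.1 (SD over 4 groups), which argues against a larger share of all other cells alike. A different share of single cell types between the animals stays open. Batch, litter, sex and age of the animals are not given in the labels, and no biological explanation was tested.

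Other splits of the same libraries were counted for each comparison. For TNF against vehicle, 2 of 35 splits called as many genes as the real one (371), and the other was the split by animal pairs, which called 3672, so chance cannot be excluded by this count alone, although the other 33 called 0. In TNF effects that share no library, 177 genes rose in both, against 3.83 for independent lists, and 68 fell in both, against 0.872. Since 0 went in opposite directions, the called changes recurred in separate libraries. These expected values treat genes as independent, and both comparisons share each gene's estimate of spread, so they do not measure chance. The blocked model, which takes the animals out, called 2692 for TNF against vehicle. In its TNF effects 990 genes rose in both, against 141, 841 fell in both, against 133, and 1 went in opposite directions. For PFM037 against vehicle and PFM037+TNF against TNF the real count was 0, so 35 of 35 splits reached it, with the animal pairs at 4777 and 1735. PFM037+TNF against PFM037 (312) and against vehicle (365) were reached by 1 of 35 splits, the real one, with 0 as the highest other. These free splits ignore that the groups share their animals, so they do not exclude chance for the paired design. For the interaction 100 of 100 splits drawn reached the real 0, and the highest called 5469. Splits calling so many genes point to a structure of the samples. Within animals, 1 of 8 label swaps, the real one, reached the blocked counts of 2692, 11, 188, 2828 and 3437, with 0, 0, 0, 1 and 0 as the highest others, and 8 swaps are too few for a share under 0.05.

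Among 668 groups of 4 values, 45 had a library far from the other 3, and chance flags about 1 in 20. With animal 1 highest in vehicle were Arg1 (72.5 CPM, next 3.07), Atp6v0d2 (10.3), Ccl7 (922), Ccl9 (1720), Cd36 (1190, next 513), Fam198b (24.7) and Il10 (14). Animal 1 was highest with PFM037 for Ccl6 (246), Ccl9 (1400), Cd36 (619), Ctsl (1680) and Dusp4 (61.8, next 31.9). With TNF it was highest for Atp6v0d2 (4.89), Ctsd (2220), Fam198b (10.9), Il10 (5.13), Sel1l3 (5.91) and Upp1 (33.6). With PFM037+TNF it was highest for Arg1 (11.2), Ctsl (949) and Fth1 (8060). It was lowest in vehicle for Alas2 (33.3, next 110).

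Animal 2 was highest for Hspa1b in vehicle (8.11), PFM037 (11.1) and PFM037+TNF (12), for Ltf in vehicle (2660), for Cenpe (80.4) and Ly6g (45.1) with PFM037, for Cd209a (1.16), Ermap (8.58) and Mpo (764) with TNF, and for Mmp9 with both (418). It was lowest for F7 in vehicle (16), Fscn1 with PFM037 (2.37), Ctsb (3750), Gas6 (5.48) and Mrc1 (6.75) with TNF, and Ctsd with both (1310). Animal 3 was highest for Bub1 (67.9) and Trim47 (12.5) in vehicle and for Itgae with PFM037 (2.23). With TNF, animal 4 was lowest for Nfkbia (398) and highest for 1 other gene (11.6). The total of vehicle 4 was 14114703 counts (14.11 when scaled, next 19.33), and the 10 most abundant genes took 8.49% of the counts of TNF 1.

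Camera's test of the interaction called 5 lists with the preset correlation, each of which was lost with an estimated correlation (adjusted p = 0.962), while blocked fry called 0 lists and 0 genes passed. Their medians were 0.18 for interferon-stimulated genes, 0.1 for macrophage maturation, -0.17 for NRF2 targets and heme catabolism, -0.29 for glycolysis and hypoxia and 0.15 for cholesterol synthesis.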

How the results depend on the processing

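Tests with the animal as a block under other tools, scalings and filters, with single animals left out or with a pair of animals alone, and the relations without an animal, were chosen only after the result was seen. No named gene or list reversed its direction while past a threshold in an alternative to the model without a block. DESeq2 called 641 genes for TNF against vehicle, 10 for PFM037+TNF against TNF, 583 against PFM037 and 783 against vehicle. With the replicate block the counts were 2692 for TNF, 11 for PFM037, 188 for PFM037+TNF against TNF, 2828 against PFM037 and 3437 against vehicle, with 88 genes that PFM037 moved against TNF, and the interaction stayed at 0. The pairing thus changed the calls given beside the results, and fry called more lists with the block in every comparison but the interaction. With only the groups compared the counts were 110 for TNF, 181 against PFM037 and 133 against vehicle, where fewer libraries inform the spread. Without a filter PFM037+TNF against vehicle had 223 calls, as more genes were tested.

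In the blocked model DESeq2 called 71 genes for PFM037 against vehicle and 421 for PFM037+TNF against TNF, and library size alone called 4 for PFM037 against vehicle. Animals 1 and 2 alone, with the replicate block, gave 1597 for TNF, 29 for PFM037, 36 for PFM037+TNF against TNF, 1270 against PFM037 and 1830 against vehicle. Animals 3 and 4 alone gave 1469 for TNF, 74 for PFM037, 592 for PFM037+TNF against TNF and 4 for the interaction. The cause was not tested.

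Leaving out single libraries gave 206 to 305 calls for TNF, 163 to 220 for PFM037+TNF against PFM037 and 160 to 311 against vehicle, with fewer samples in each. Leaving out an animal in the blocked model gave 1581 to 2294 for TNF, 0 to 6 for PFM037, 1 to 60 for PFM037+TNF against TNF, 1434 to 2464 against PFM037 and 2045 to 2950 against vehicle. The correlation of the PFM037 effects with and without TNF was 0.26 to 0.314 without 1 animal and 0.649 under the stricter filter. For the TNF effects it was 0.672 to 0.73 and 0.915, and for TNF and PFM037 against vehicle 0.059 to 0.148 and -0.101. Among lists, library size alone lost dendritic markers for PFM037 and interferon-stimulated genes for PFM037+TNF against TNF. It added 2 lists for PFM037+TNF against TNF and 2 against PFM037. Depth limits low genes most in TNF 4, PFM037 3 and TNF 3.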

Other observations

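The gene-by-gene differences between animals and the choice of animal pairs were made only after the result was seen, and these pairs are not groups of the study.

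Between the 8 libraries of animals 3 and 4 and the 8 of animals 1 and 2, 1187 genes were higher in all and 1402 lower in all, 408 and 218 of them by more than 2-fold. Ifit3, which encodes an antiviral protein, differed by 5.29 on the log2 scale, the macrophage sialic acid receptor Siglec1 by 4.75, the interferon regulator Irf7 by 3.96 and Oasl2 by 3.57. Lower in animals 3 and 4 were the eosinophil genes Prg2 (-2.17) and Epx (-2.13), the ribonucleases Ear1 (-2.52) and Ear2 (-2.47), Alox15 (-2.44) and the basophil proteases Prss34 (-1.7) and Mcpt8 (-1.66). These genes were chosen after their values were seen.

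Among gene lists, MHC class I differed by 1.01 ± 0.23 (SD over 4 groups), glycolysis and hypoxia by 0.98 ± 0.23, macrophage maturation by 0.73 ± 0.23 and NF-kB targets by 0.52 ± 0.33, all higher in animals 3 and 4 in 4 of 4 groups. Neutrophil and granule genes (-0.58 ± 0.19), cell cycle genes (-0.42 ± 0.13) and mitochondrially encoded genes (-0.61 ± 0.37) were lower in 4 of 4. Ribosomal protein genes took 2.42% to 3.36% of counts in animals 1 and 2 and 1.75% to 2.26% in animals 3 and 4.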
